A study of Mus musculus with 53 samples.

How the data were processed

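RNA from 53 snap-frozen livers of male C57BL/6J mice was sequenced in 3 experiments, 1 library per liver. Groups were taken from the labels: 9 wild-type livers on low-fat diet, 7 wild-type and 7 labelled knockout on Western diet, 6 wild-type after olive oil, 4 wild-type and 6 labelled knockout after CCl4, and 5 wild-type at day 0, 5 wild-type at day 3 and 4 labelled knockout at day 3 of partial hepatectomy. The authors deposited raw read counts per Ensembl gene, with no normalization. Per the labels, reads were aligned with TopHat2 2.0.11 to GRCm38 and counted with HTSeq, whose version is not stated. The annotation release, the strand setting and filters are not stated either. The diet and CCl4 tables hold 38293 genes each and that of hepatectomy holds 53379, so it was counted on another annotation, and 36410 genes are in all 3.

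Total counts per library ran from 8963187 to 15196537 in the diet experiment, from 2661699 to 6364414 in the CCl4 experiment and from 2450358 to 6914274 in the hepatectomy experiment. The 10 most abundant genes took 16.1% to 25.0% of the counts. No pair of libraries of a group differed by as little as counting error alone would give, with a lowest chi-square per degree of freedom of 5.27. A count of 0 was taken to allow up to 3 counts (95% confidence). Symbols and positions came from GENCODE vM21, which holds 36429 of the 38293 identifiers and 53274 of the 53379.

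Each experiment was fitted alone in edgeR 4.0.16 (R 4.3.3) with its 3 groups in 1 model, TMM normalization, filterByExpr and the quasi-likelihood F-test, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Levels are TMM-normalized CPM. Differences in the response to the knockout label between challenges were tested in a joint fit of the 53 libraries. Bmp8b was compared with exact two-sided permutation tests of log2(CPM + 0.5). Genes called within 10 Mb of Bmp8b were compared with all others by Fisher's exact test. The sequences of BC002163 and Ndufs5 were aligned with BLAST 2.17.0.

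Gene lists, 38 in all, were tested with fry of limma 3.58.1 where at least 5 members were measured, adjusted over the lists of a comparison. Beside it, camera was run with an estimated correlation and with a preset correlation of 0.01. The comparisons, tests, lists and most alternatives were chosen before the data were examined. The named genes follow a rule set at the same time: Bmp8b and Bmp8a; the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM in a group and no overlap between groups; and up to 4 members with the smallest p from the BMP target list and from up to 8 further lists. Fewer are named than the rule gives, and 7 genes with only a few counts in a control group were left out after their values were seen.

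The tests were tried on simulated data with known changes, where 2.5% to 8.8% of calls were false. The simulated genes varied independently, with no variation shared by the genes of a library, so these rates need not hold for the real livers. The alternatives were DESeq2 1.42.0 size factors and tests, no filter, a filter of 1 CPM, a fold threshold of 1.5, a fit of only 2 groups, robust dispersion, limma voom with quality weights, the i5 index as a covariate and leaving out each library in turn. Titles give the day 0 and day 3 wild-type livers the same mouse numbers, 12 to 16, and the mouse number was used as a block in an alternative. For 13 and 14 only the day 3 title adds an N to the number, so the titles leave these pairs uncertain. After removing group means, the livers of a number correlated at 0.118 for mouse 16, 0.057 for 12, 0.017 for 13, -0.032 for 14 and 0.088 for 15. Mice 15 and 16 matched their own number best. For 12, 13 and 14 another number correlated better: 14 at 0.065, 14 at 0.053 and 16 at 0.039. The correlations thus do not identify these pairs. Other splits of the libraries, 100 drawn per comparison, were tested in the same way. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. No library was left out.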

Results

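Messenger RNA was measured by sequencing in 53 whole-liver libraries, each from snap-frozen tissue of male C57BL/6J mice, in 3 experiments. In the diet experiment, mice ate a Western diet or a low-fat control diet for 32 weeks. It holds 9 wild-type livers on low-fat diet, 7 wild-type livers on Western diet and 7 livers labelled Bmp8b knockout on Western diet. In the toxin experiment, mice received carbon tetrachloride (CCl4, a liver toxin activated in hepatocytes) in olive oil, or olive oil alone, and were culled 3 days later. It holds 6 wild-type livers after olive oil, 4 wild-type livers after CCl4 and 6 livers labelled knockout after CCl4. In the surgery experiment, liver was taken at partial hepatectomy (removal of part of the liver, called day 0 here) and 3 days after it. It holds 5 wild-type livers at day 0, 5 wild-type livers at day 3 and 4 livers labelled knockout at day 3. Levels are in CPM, the counts of a gene scaled to the normalized library total.

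Bmp8b, the targeted gene, encodes a secreted ligand of the bone morphogenetic protein (BMP) family and lies on chromosome 4 from 123105165 to 123132099 (GRCm38, ENSMUSG00000002384). Its normalized level was low in every group and was not lower in the livers labelled knockout. In the diet experiment it was 0.128 ± 0.130 CPM (mean ± SD, n = 9) on low-fat diet, 1.07 ± 0.491 (n = 7) in wild-type livers on Western diet and 1.53 ± 0.523 (n = 7) in livers labelled knockout. After olive oil none of the 6 libraries held a Bmp8b count, which allows a level of up to 0.821 CPM in the shallowest of them by counting error alone. After CCl4 the level was 0.464 ± 0.629 CPM (n = 4) in wild-type livers and 1.18 ± 1.04 (n = 6) in livers labelled knockout. At day 0 of the surgery it was 0.210 ± 0.327 CPM (n = 5), and at day 3 it was 0.848 ± 0.407 (n = 5) in wild-type livers and 2.12 ± 0.703 (n = 4) in livers labelled knockout.

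Western diet raised Bmp8b in wild-type livers, with a log2 fold change of 2.99 and an adjusted p of 3.80e-05 by edgeR, and with an exact two-sided permutation p of 8.74e-05. Between the labelled knockout and wild-type livers, the exact permutation p for Bmp8b was 0.135 on Western diet, 0.214 after CCl4 and 0.0397 after hepatectomy, each time with the higher mean in the livers labelled knockout. In wild-type livers the exact permutation p was 0.133 for CCl4 against olive oil and 0.0317 for day 3 against day 0, the latter ignoring the shared mouse numbers, with no paired test run. These are 6 tests, unadjusted, and edgeR with no filter on low counts gave adjusted p = 0.333 for day 3 against day 0 and 0.692 for labelled knockout against wild type at day 3. The paralog Bmp8a had 1 count in all 53 libraries. Gene totals do not show which exons the Bmp8b reads came from, so they do not check the knockout labels, and the groups are called labelled knockout throughout.

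**Figure D1:**
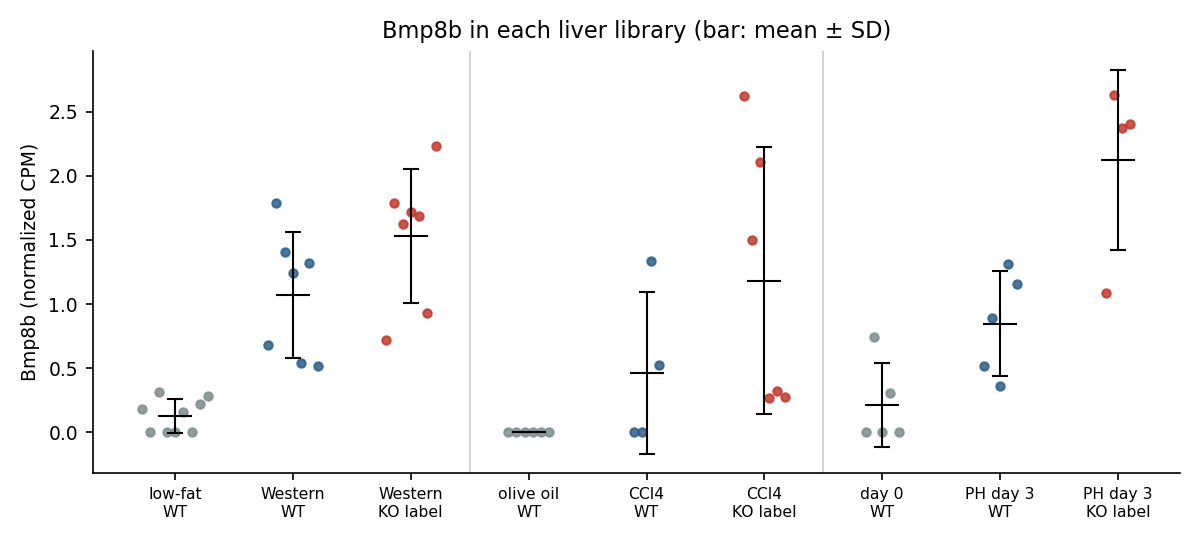
Bmp8b in each of the 53 libraries, in normalized CPM, by group. Points are libraries, horizontal bars are group means and error bars are SD. The mean rose from 0.128 to 1.07 with Western diet in wild-type livers and was 1.53, 1.18 and 2.12 in the groups labelled knockout.

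The diet experiment asked how 32 weeks of Western diet, which loads the liver with fat, change the wild-type liver. Macrophage, matrix and inflammatory genes rose and hepatocyte genes fell. Gpnmb, a glycoprotein of lipid-loaded macrophages, rose from 0.894 ± 0.475 CPM (SD, n = 9) on low-fat diet to 38.9 ± 21.5 (n = 7) on Western diet, a log2 fold change of 5.40 with SE 0.60. Hsd3b5, a steroid dehydrogenase of male mouse liver, fell from 155.9 ± 96.8 to 3.18 ± 5.91 CPM, a log2 fold change of -5.65 with SE 1.02 (-7.31 without Western wild-type liver 32). Albumin (Alb), the main plasma protein made by hepatocytes, fell from 86230 ± 10320 to 55990 ± 10710 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4869 of 13005 genes differed, 2656 higher and 2213 lower on Western diet.

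Among markers of monocyte-derived and lipid-associated macrophages, 13 of 14 measured genes rose and 1 fell (13 and 1 adjusted over the list alone). Trem2, a lipid-sensing receptor, rose 14.5-fold, Mmp12, a macrophage elastase, 18.6-fold, and Lpl, lipoprotein lipase, 6.61-fold. The rotation test fry gave this list adjusted p = 2.45e-05. The test camera, which sets a list against the other genes, gave adjusted p = 0.175 with an estimated correlation between genes, here and below. Of 31 collagen and matrix genes, 27 rose and 2 fell (29 and 2 adjusted over the list alone), with fry adjusted p = 2.83e-05 and adjusted p = 0.175 with an estimated correlation. They include Col1a2, a chain of type I collagen, at 5.48-fold and Sparc, a collagen-binding protein, at 2.38-fold, and Timp1, an inhibitor of matrix-degrading enzymes, at 29.2-fold from a level of 0.0959 CPM (log2 fold change 4.87, and 5.76 without low-fat liver 18). Of 12 TGF-beta pathway genes, 10 rose (11 adjusted over the list alone), among them the receptor Tgfbr2 at 1.92-fold, with fry adjusted p = 2.45e-05 and adjusted p = 0.175 with an estimated correlation.

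Of 18 inflammatory cytokine and chemokine genes, 17 rose (18 adjusted over the list alone), with fry adjusted p = 7.55e-05 and adjusted p = 0.200 with an estimated correlation. Il1rn, the interleukin-1 receptor antagonist, rose 5.49-fold and Vcam1, an adhesion molecule, 3.24-fold. Of 18 acute phase genes, which the liver secretes in inflammation, 11 rose and 4 fell (the same 11 and 4 counts adjusted over the list alone), with fry adjusted p = 1.70e-05 and adjusted p = 0.175 with an estimated correlation. Lcn2 rose 20.1-fold, Orm3 10.96-fold and Saa1 6.06-fold. Of 14 lipid droplet and lipid uptake genes, 10 rose (11 adjusted over the list alone), with fry adjusted p = 1.81e-05 and adjusted p = 0.175 with an estimated correlation. The droplet proteins Plin4 and Cidec rose 7.15-fold and 7.77-fold, the fatty acid transporter Cd36 2.55-fold and the lipid-regulating nuclear receptor Pparg 2.23-fold. Of 10 quiescent stellate cell markers, 6 rose (6 adjusted over the list alone), among them Hgf at 2.14-fold and Lrat, which stores retinol as esters, at 1.78-fold, with fry adjusted p = 2.84e-06 and adjusted p = 0.175 with an estimated correlation.

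Of 14 genes of hepatocyte identity and secreted proteins, 11 fell (12 adjusted over the list alone), with fry adjusted p = 1.77e-05 and adjusted p = 0.175 with an estimated correlation. Besides Alb at 1.54-fold lower, they include Tat, a tyrosine-degrading enzyme, at 2.37-fold lower and Hnf4a, a hepatocyte transcription factor, at 1.43-fold lower. Of 11 male-biased liver genes, 6 fell (6 adjusted over the list alone), with fry adjusted p = 0.00204 and adjusted p = 0.263 with an estimated correlation. One of them, Mup21, was 7.52-fold lower, but it belongs to a family of near-identical genes whose reads may be split. Of 18 bile acid synthesis and transport genes, 10 fell and 2 rose (10 and 2 adjusted over the list alone), with fry adjusted p = 0.00145 and adjusted p = 0.263 with an estimated correlation. The sinusoidal transporter Slco1a1 was 7.81-fold lower. Of 12 BMP-SMAD target genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone), with fry adjusted p = 0.234. Hepcidin (Hamp), the iron hormone induced by BMP signals, was 3.12-fold lower, its neighbour Hamp2 3.77-fold lower, and Bmper, a BMP-binding protein, 3.55-fold higher.

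No list on Western diet passed by camera with an estimated correlation. That test asks whether a list changed more than the other genes, of which many changed (4869 of 13005 called), so it does not undo the fry results. With a fold threshold of 1.5, 990 genes remained called, 887 higher and 103 lower. Within the libraries of i5 index D501 the count was 3645 and within those of D502 it was 1401. Libraries on Western diet varied: on the first principal component, wild-type livers 32 and 36 lay between the low-fat livers and the other wild-type livers on Western diet.

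**Figure D2:**
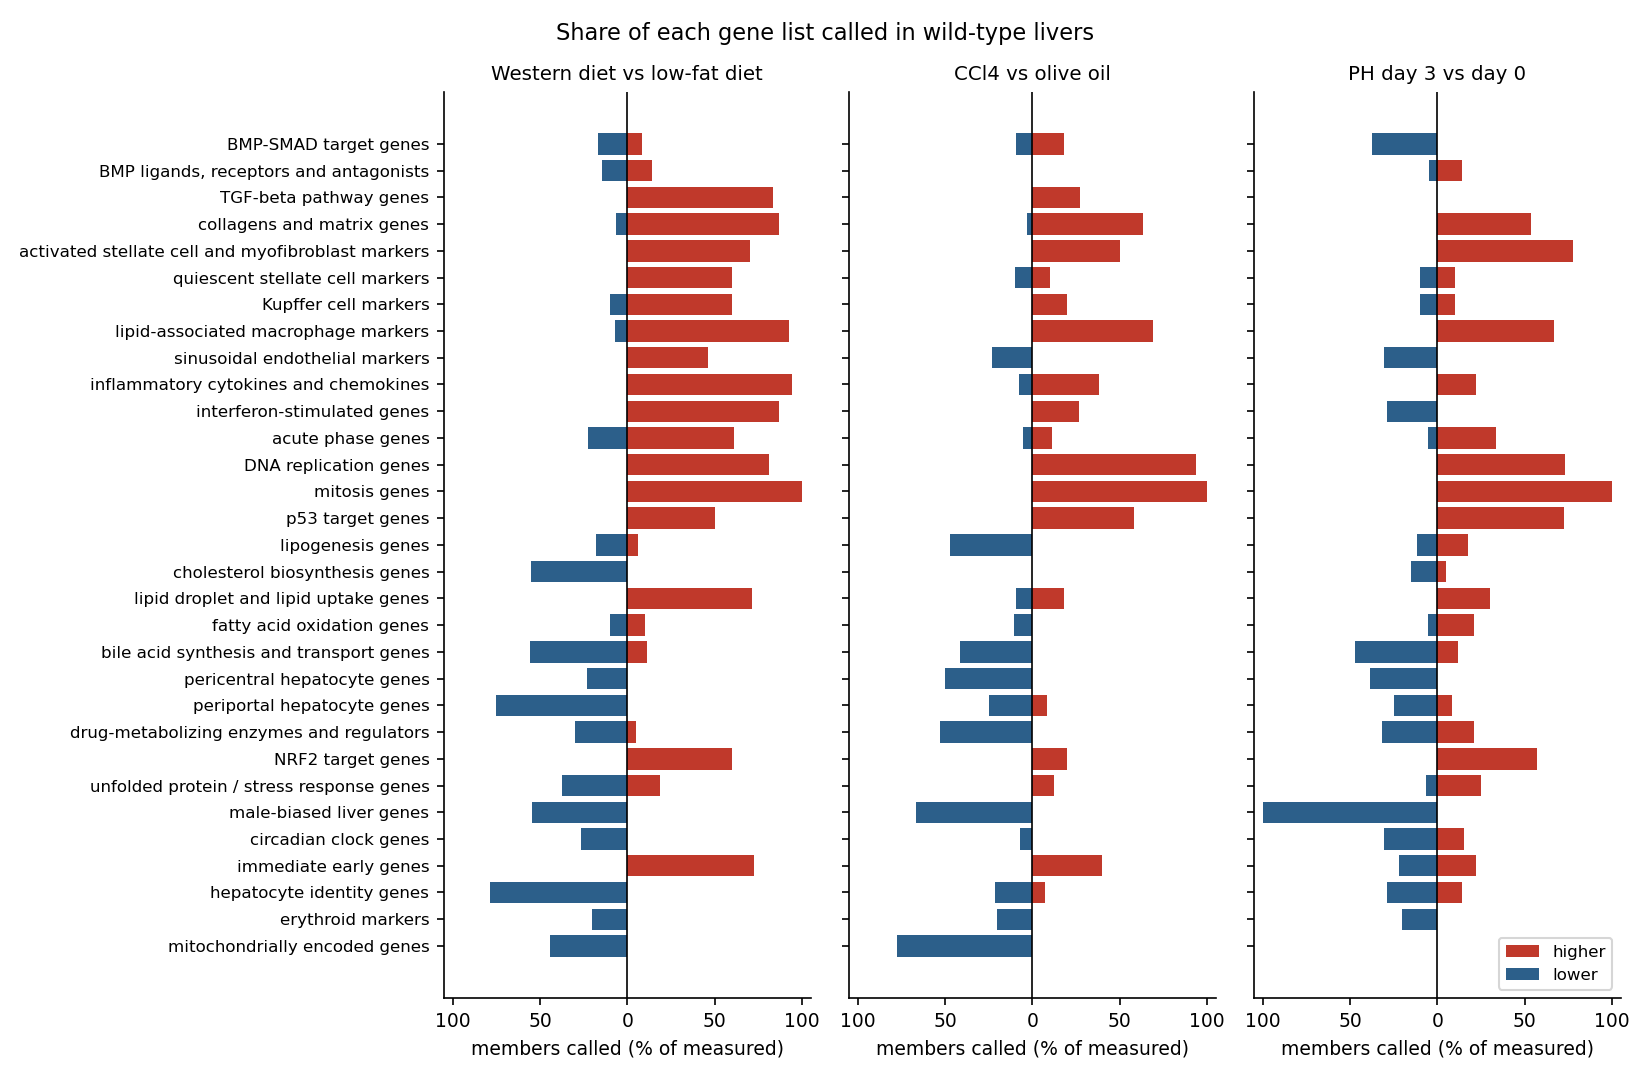
Share of each gene list called higher (red) or lower (blue) by edgeR in wild-type livers, in percent of the measured members, for lists with at least 5 measured members in each experiment. All 18 mitosis genes rose in each of the 3 comparisons.

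The comparison of livers labelled knockout with wild-type livers on Western diet asked which genes differ by label in the fatty liver. No experiment holds unchallenged livers labelled knockout, so a difference may have been present before the challenge. edgeR called 2 of 13005 genes, both higher in livers labelled knockout, and 766 genes had an unadjusted p under 0.05 (468 without labelled knockout liver 1 and 1418 without 35). BC002163, a processed pseudogene on chromosome 16 from 42955631 to 42955949 (ENSMUSG00000081824), was at 8.36 ± 1.26 CPM (SD, n = 7) against 0.386 ± 0.252 (n = 7), a log2 fold change of 4.45 with SE 0.32 and edgeR adjusted p = 3.58e-09. Utp11, which takes part in ribosome assembly, lies on chromosome 4 from 124678160 to 124693600, 1.57 Mb from Bmp8b (ENSMUSG00000028907). It was at 26.3 ± 2.11 CPM against 17.1 ± 1.43, a log2 fold change of 0.62 with SE 0.08 and edgeR adjusted p = 0.00047. limma voom with quality weights called 2 genes and DESeq2 called 3.

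No gene list differed between these groups by fry. Of the 12 BMP-SMAD target genes 0 were called (0 adjusted over the list alone, fry adjusted p = 0.757), and Hamp was at 229 ± 153 CPM in livers labelled knockout against 168 ± 91.9. Of 31 collagen and matrix genes 0 were called (0 adjusted over the list alone, fry adjusted p = 0.582), and of 14 macrophage markers 0 were called (0 adjusted over the list alone, fry adjusted p = 0.582). Labelled knockout liver 1 resembled the low-fat livers. Its mean log2 difference from them was -0.25 over the matrix genes and -0.17 over the macrophage markers. The other livers labelled knockout were at 0.82 to 1.88 and at 1.18 to 2.70. The cause was not tested. In simulated libraries of these groups, the same test recovered 82.1% of genes changed 2-fold and 47.8% of genes changed 1.5-fold. That simulation changed 67 genes at each of these folds and 66 at 4-fold, and 156 were called. With few true changes the adjustment is stricter, so these shares may overstate recovery here.

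The toxin experiment asked what wild-type liver expresses 3 days after CCl4. Macrophage and matrix genes and genes of dividing cells rose, and genes of the hepatocytes around the central vein and of drug metabolism fell. Gpnmb rose from 0.360 ± 0.263 CPM (SD, n = 6) after olive oil to 60.5 ± 26.0 (n = 4) after CCl4, a log2 fold change of 7.30 with SE 0.56. Slc1a2, a glutamate transporter of pericentral hepatocytes, fell from 161 ± 69.8 to 0.906 ± 1.24 CPM, a log2 fold change of -7.57 with SE 0.71 (-8.99 without CCl4 liver 4). Cyp2e1, the enzyme that activates CCl4, fell from 6285 ± 2308 to 639 ± 210 CPM. edgeR called 2331 of 11663 genes, 1296 higher and 1035 lower after CCl4.

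Of 13 monocyte-derived and lipid-associated macrophage markers, 9 rose (9 adjusted over the list alone), with fry adjusted p = 4.30e-06 and adjusted p = 0.00925 with an estimated correlation. Trem2 rose 11.04-fold, Mmp12 10.2-fold and Cd63, a lysosomal membrane protein, 19.7-fold. Of 30 collagen and matrix genes, 19 rose and 1 fell (23 and 1 adjusted over the list alone), with fry adjusted p = 4.95e-05 and adjusted p = 0.0303 with an estimated correlation. Col1a1 rose 10.3-fold and Col3a1 7.68-fold. Of 12 p53 target genes, 7 rose (8 adjusted over the list alone), with fry adjusted p = 3.88e-06 and adjusted p = 0.00925 with an estimated correlation. Cdkn1a, a cell cycle inhibitor, rose 13.4-fold and Phlda3, an inhibitor of Akt signalling, 10.4-fold (log2 fold change 3.38, and 4.37 without olive oil liver 26).

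Of 12 pericentral hepatocyte genes, 6 fell (6 adjusted over the list alone), with fry adjusted p = 4.95e-05 and adjusted p = 0.0295 with an estimated correlation. Besides Slc1a2 they include Cyp2e1 at 9.84-fold lower and Glul, glutamine synthetase, at 9.03-fold lower (log2 fold change -3.17, and -3.77 without CCl4 liver 34). Of 19 drug-metabolizing enzymes and their regulators, 10 fell (10 adjusted over the list alone), with fry adjusted p = 3.56e-05 and adjusted p = 0.0295 with an estimated correlation. Cyp2a5 was 64.2-fold lower (log2 fold change -6.00, and -6.83 without CCl4 liver 7), Cyp2c37 13.0-fold lower and the bilirubin-conjugating Ugt1a1 2.28-fold lower. Of 12 male-biased liver genes, 8 fell (8 adjusted over the list alone), with fry adjusted p = 4.95e-05 and adjusted p = 0.0295 with an estimated correlation. They include Cyp4a12b at 71.1-fold lower and Elovl3, a fatty acid elongase, at 36.2-fold lower. Without CCl4 liver 5 their log2 fold changes went from -6.15 to -6.94 and from -5.18 to -6.03. Cyp2a5, Cyp2c37, Ugt1a1 and Cyp4a12b have close paralogs or shared exons, so their counts are uncertain.

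Of 17 bile acid synthesis and transport genes, 7 fell (10 adjusted over the list alone), with fry adjusted p = 2.37e-05 and adjusted p = 0.0250 with an estimated correlation. The sodium-bile acid transporter Slc10a1 was 2.51-fold lower, the bile acid ligase Slc27a5 2.55-fold lower and Cyp7b1 4.48-fold lower. Of 9 mitochondrially encoded genes, 7 fell (9 adjusted over the list alone), with fry adjusted p = 3.56e-05 and adjusted p = 0.184 with an estimated correlation. Among them mt-Co1 was 1.78-fold lower and mt-Nd2 1.95-fold lower. Of 11 BMP-SMAD target genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with fry adjusted p = 0.638. Id1 was 2.98-fold higher, Bmper 73.0-fold higher and Hamp2 15.5-fold lower, and the calls of Id1 and Bmper were each lost in 7 of the fits that left out 1 library, and without CCl4 wild-type liver 34 the log2 fold change of Bmper went from 6.19 to 3.45 (adjusted p = 0.271), and without olive oil liver 29 to 7.37.

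All 18 mitosis genes rose (18 adjusted over the list alone), with fry adjusted p = 0.00402 and adjusted p = 0.170 with an estimated correlation. Of 16 DNA replication genes, 15 rose (15 adjusted over the list alone), with fry adjusted p = 0.00514 and adjusted p = 0.184 with an estimated correlation. CCl4 wild-type liver 34 stood apart from the other CCl4 livers in these groups. Its mean log2 difference from the olive oil livers over the mitosis genes was 0.70, against 4.84, 5.96 and 6.53 in the other CCl4 wild-type livers. The i5 index was not balanced, since index D503 held CCl4 livers only. With the index as a covariate 3599 genes were called, 1647 of them among the 2331, but that fit rests on livers 22, 34 and 35, the CCl4 livers that share an index with olive oil livers, and 34 and 35 are the pair that stood apart.

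**Figure D3:**
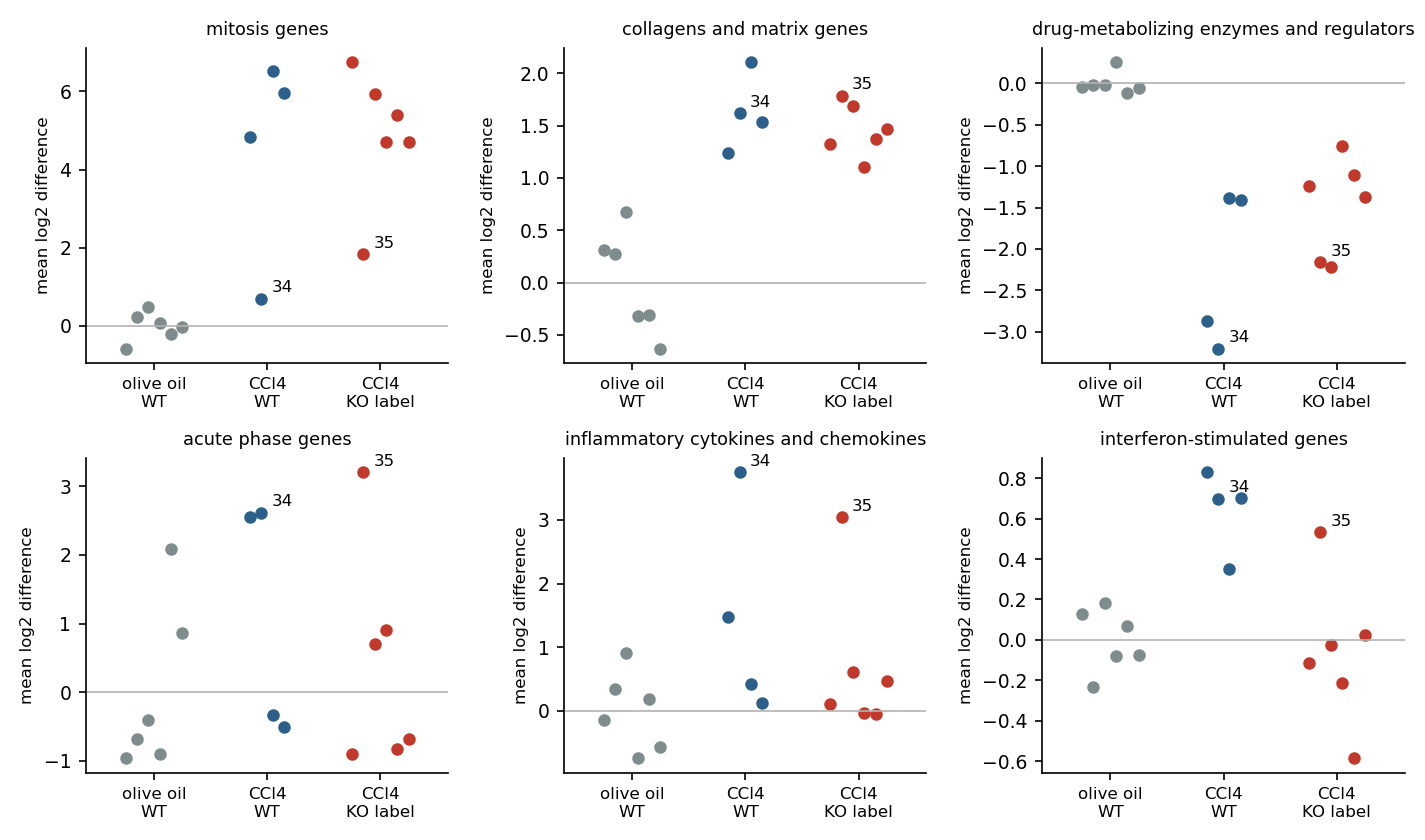
Mean log2 difference from the mean of the olive oil livers over the genes of 6 lists, 1 point per library, for olive oil wild-type, CCl4 wild-type and CCl4 livers labelled knockout. Livers 34 and 35 are numbered. Over the mitosis genes they were at 0.70 and 1.84, and the other 8 CCl4 livers were at 4.70 to 6.75.

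Livers labelled knockout were compared with wild-type livers after CCl4, to ask which genes differ by label in acute damage. Without livers labelled knockout after olive oil, a difference cannot be tied to the damage. edgeR called 1 of 11663 genes, and 719 had an unadjusted p under 0.05 (1737 without labelled knockout liver 35 and 1369 with the i5 index as a covariate). The called gene was again BC002163, at 8.06 ± 2.09 CPM (SD, n = 6) in livers labelled knockout against 0.205 ± 0.147 (n = 4) in wild-type livers, a log2 fold change of 5.21 with SE 0.67 and edgeR adjusted p = 0.00446. limma voom with quality weights called 2 genes, and DESeq2 called 21 without BC002163. Within index D503 edgeR called 0 genes, with 734 at an unadjusted p under 0.05, and BC002163 had a log2 fold change of 5.33 (edgeR adjusted p = 0.0531).

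Interferon-stimulated genes, the antiviral response genes, were the list that differed by fry in this comparison. Their median log2 fold change was -0.66 over 15 measured genes, with fry adjusted p = 0.00609 and adjusted p = 0.00818 with an estimated correlation, and 0 of the 15 were called over all genes and 1 was lower adjusted over the list alone. Isg15, a ubiquitin-like antiviral protein, was at 9.08 ± 4.67 CPM in livers labelled knockout against 25.4 ± 17.7 in wild-type livers, with a log2 fold change of -1.48 and adjusted p = 0.654. Oas1a was at 4.25 ± 1.36 against 8.30 ± 0.867 CPM, Irf7 at 41.4 ± 19.6 against 77.7 ± 43.1 and Oasl2 at 7.30 ± 3.19 against 11.6 ± 1.72, each with an adjusted p over 0.7. The list kept an adjusted p between 0.000729 and 0.0341 when each library was left out in turn, and 0.0264 with the i5 index as a covariate. In wild-type livers 4 of the 15 genes rose with CCl4 (5 adjusted over the list alone), with fry adjusted p = 0.0028 and adjusted p = 0.184 with an estimated correlation. In simulated libraries of these 2 groups, the gene test recovered 35.8% of genes changed 2-fold and 69.7% of genes changed 4-fold. That simulation changed 67 genes 1.5-fold, 67 genes 2-fold and 66 genes 4-fold, and 80 were called. With few true changes the adjustment is stricter, so these shares may overstate recovery here.

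The surgery experiment asked what the regenerating wild-type liver expresses 3 days after partial hepatectomy. Genes of dividing cells and p53 targets rose, and all measured male-biased genes fell. Mki67, a marker of cycling cells, rose from 2.15 ± 2.23 CPM (SD, n = 5) at day 0 to 61.1 ± 22.4 (n = 5) at day 3, a log2 fold change of 4.82 with SE 0.41. Hsd3b5 fell from 354.5 ± 44.8 to 34.3 ± 9.68 CPM, a log2 fold change of -3.36 with SE 0.20. edgeR called 1915 of 11026 genes, 1088 higher and 827 lower at day 3. The day 3 livers were all sequenced with i5 index D507 and the day 0 livers with D505 or D506, so index and day cannot be told apart.

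All 18 mitosis genes rose (18 adjusted over the list alone), with fry adjusted p = 2.09e-05 and adjusted p = 0.00783 with an estimated correlation. The mitotic kinase Cdk1 rose 28.4-fold and Ccna2, cyclin A2, 14.5-fold. Of 15 DNA replication genes, 11 rose (14 adjusted over the list alone), with fry adjusted p = 0.000284 and adjusted p = 0.0785 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, rose 6.30-fold and Mcm2, a replicative helicase subunit, 2.68-fold. Of 11 p53 target genes, 8 rose (9 adjusted over the list alone), with fry adjusted p = 1.09e-05 and adjusted p = 0.00783 with an estimated correlation. Cdkn1a rose 8.72-fold, Eda2r 12.2-fold and Btg2 2.70-fold. Without day 0 liver 15 the log2 fold change was 5.65 for Mki67 and 4.62 for Eda2r, against 4.82 and 3.61 with it. Outside the lists, Arrdc3, an arrestin-like protein, was 5.71-fold lower.

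Of 14 targets of NRF2, the regulator of antioxidant genes, 8 rose (9 adjusted over the list alone), with fry adjusted p = 0.00115 and adjusted p = 0.113 with an estimated correlation. The glutathione transferase Gstm3 rose 10.9-fold, and it has close paralogs, so its count is uncertain. The heme-degrading enzyme Hmox1 rose 2.23-fold. Of 6 macrophage markers, 4 rose (5 adjusted over the list alone), with fry adjusted p = 8.30e-05 and adjusted p = 0.0223 with an estimated correlation. Lpl rose 3.80-fold, Cd9 2.45-fold and Atp6v0d2, a proton pump subunit, 7.65-fold.

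All 12 male-biased genes fell (12 adjusted over the list alone), with fry adjusted p = 3.25e-05 and adjusted p = 0.00783 with an estimated correlation. Elovl3 was 3.39-fold lower and Mup20, of the same gene family as Mup21, 3.202-fold lower. Of 17 bile acid genes, 8 fell and 2 rose (9 and 3 adjusted over the list alone), with fry adjusted p = 0.00115 and adjusted p = 0.113 with an estimated correlation. Cyp7b1 was 3.72-fold lower and Slco1a1 3.53-fold lower, and Akr1d1 was 1.77-fold higher. Of 13 pericentral genes, 5 fell (6 adjusted over the list alone), with fry adjusted p = 0.00182 and adjusted p = 0.165 with an estimated correlation. Cyp2e1 was 2.42-fold lower, Glul 1.85-fold lower and Cyp1a2 1.61-fold lower. Of 8 BMP-SMAD target genes, 3 fell (5 adjusted over the list alone), with fry adjusted p = 0.0234 and adjusted p = 0.296 with an estimated correlation. Hamp was 4.13-fold lower, Id2 2.03-fold lower and Id3 2.10-fold lower, and the call of Id3 was lost in 7 of the fits that left out 1 library.

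Livers labelled knockout were compared with wild-type livers 3 days after hepatectomy, to ask which genes differ by label in regeneration. Without livers labelled knockout at day 0, a difference cannot be tied to regeneration. edgeR called 17 of 11026 genes, 13 higher and 4 lower in livers labelled knockout (n = 4) than in wild-type livers (n = 5), and 1001 had an unadjusted p under 0.05. BC002163 was at 9.06 ± 2.82 CPM (SD) against 0.468 ± 0.556, a log2 fold change of 4.29 with SE 0.59 (5.16 without wild-type liver 14) and edgeR adjusted p = 0.00191. Ndufs5, a subunit of mitochondrial complex I on chromosome 4 from 123712710 to 123718202 (ENSMUSG00000028648), was at 0.167 ± 0.199 CPM against 5.02 ± 1.44, a log2 fold change of -4.69 with SE 0.69 and edgeR adjusted p = 0.00191. The livers labelled knockout held 2 counts of it in all. BC002163 is 99.4% identical to Ndufs5 over 319 bases, so reads of Ndufs5 may have been counted there. It held 98.2% of the sum of both genes in livers labelled knockout and 8.5% in wild-type livers. C77080, on chromosome 4 from 129219578 to 129261404 (ENSMUSG00000050390), was at 53.02 ± 9.96 CPM against 103.9 ± 9.35, a log2 fold change of -0.97 with SE 0.13 and edgeR adjusted p = 0.00191. These 3 genes were called in all 9 fits that left out 1 library each, and the other 14 were not.

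Of 19 fatty acid oxidation genes, 4 were higher in livers labelled knockout (6 adjusted over the list alone), with fry adjusted p = 0.0297 and adjusted p = 0.0722 with an estimated correlation. Cyp4a14 and Cyp4a10, fatty acid hydroxylases with close paralogs, were 6.65-fold and 2.58-fold higher, and the peroxisomal enzymes Acaa1b and Ehhadh 1.57-fold and 1.56-fold higher. Further genes with a higher level were Aldh3a2, a fatty aldehyde dehydrogenase, at 1.80-fold, the nuclear receptor Nr0b2 at 2.85-fold, the carboxylesterase Ces1e at 1.68-fold, the kinase Sgk2 at 1.63-fold and Hyi at 1.69-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 3.48-fold lower (log2 fold change -1.80, and -2.47 without labelled knockout liver 17) and the ferritin receptor Scara5 2.31-fold lower. The number of called genes ranged from 3 without wild-type liver 15 or labelled knockout liver 20 to 40 without labelled knockout liver 17, and with no filter on low counts 182 were called, 66 higher and 116 lower.

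Macrophage markers had a negative median in livers labelled knockout, with fry adjusted p = 0.0355 and adjusted p = 0.0657 with an estimated correlation. Over their 6 genes the median log2 fold change was -0.59, with 0 called and 2 lower adjusted over the list alone. Lpl was at 64.6 ± 27.6 CPM against 108.9 ± 47.9, and Spp1, osteopontin, at 117 ± 17.3 against 192 ± 53.6. Lpl was at 192.6 CPM in wild-type liver 12, with the next wild-type liver at 100.1. The fry call of the macrophage list was lost without wild-type liver 12 or 13 or labelled knockout liver 19 or 20. Of the 8 BMP-SMAD target genes 0 were called and 1 was higher adjusted over the list alone, with fry adjusted p = 0.596. Id2 was at 125 ± 28.3 CPM against 81.3 ± 24.5, with edgeR adjusted p = 0.281. The list of fatty acid oxidation genes passed in 5 of the fits that left out 1 of the 9 libraries, with adjusted p = 0.0660 without wild-type liver 12, 0.0577 without 13, 0.0762 without labelled knockout liver 19 and 0.0598 without 20.

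Genes called between labelled knockout and wild-type livers lay near Bmp8b more often than elsewhere after hepatectomy, where 5 of 188 tested genes within 10 Mb of Bmp8b were called against 12 of 10838 elsewhere (Fisher's exact two-sided p = 7.16e-06). With each library left out, 2 to 5 near genes were called, 2 without wild-type liver 15 or labelled knockout liver 20 and 3 without wild-type liver 12, 13, 14 or 16 or labelled knockout liver 18 or 19, and Fisher's exact p was at most 0.0115. The 5 were C77080, Ndufs5, Cyp4a14, Cyp4a10 and Hyi, and Nr0b2 lies 10.4 Mb away. Cyp4a14 and Cyp4a10 lie close together, at -7.62 and -7.59 Mb from Bmp8b. Fisher's test counts them as independent, so its p may be too small. On Western diet 1 of 209 was called, Utp11, against 1 of 12796 elsewhere (Fisher's exact p = 0.0319, with 0.0133 within 5 Mb but 0.0589 within 20 Mb). For genes at an unadjusted p under 0.01 there, Fisher's exact p was 0.0098 within 5 Mb, 0.0511 within 10 Mb and 0.00131 within 20 Mb. After CCl4 0 of 197 were called against 1 of 11466 (Fisher's exact p = 1). BC002163 separated the labels in all 3 experiments: its lowest level among the 17 libraries labelled knockout was 4.93 CPM and its highest among the 36 wild-type libraries was 1.64 CPM. Ndufs5, 0.61 Mb from Bmp8b and chosen for the other experiments after its values were seen, was at 9.08 ± 2.98 CPM against 15.7 ± 2.95 on Western diet (edgeR adjusted p = 0.261) and at 7.78 ± 1.46 against 10.9 ± 5.43 after CCl4 (edgeR adjusted p = 0.814).

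**Figure D4:**
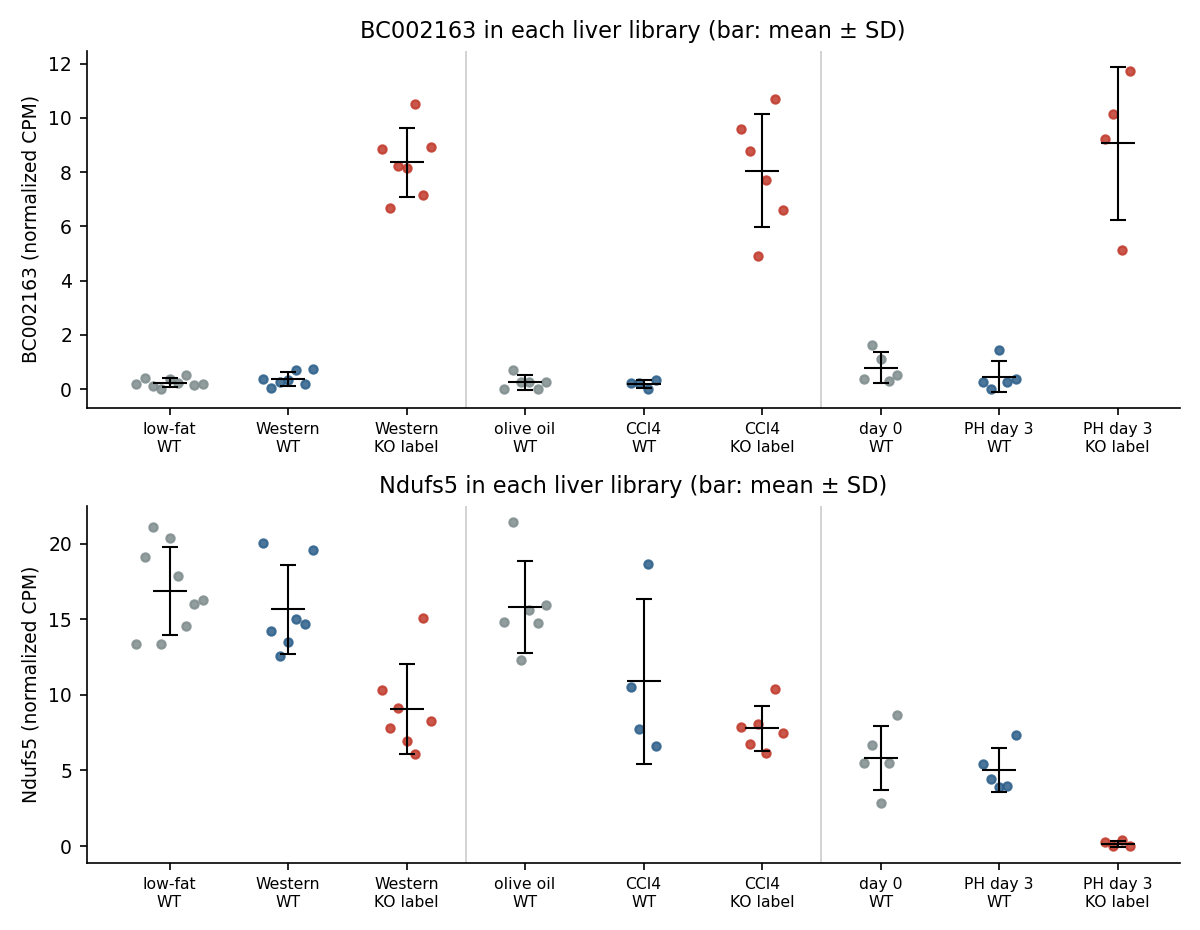
BC002163 and Ndufs5 in each of the 53 libraries, in normalized CPM, by group. Points are libraries, horizontal bars are means and error bars are SD. BC002163 was at 4.93 or more in every library labelled knockout and at 1.64 or less in every wild-type library.

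**Figure D5:**
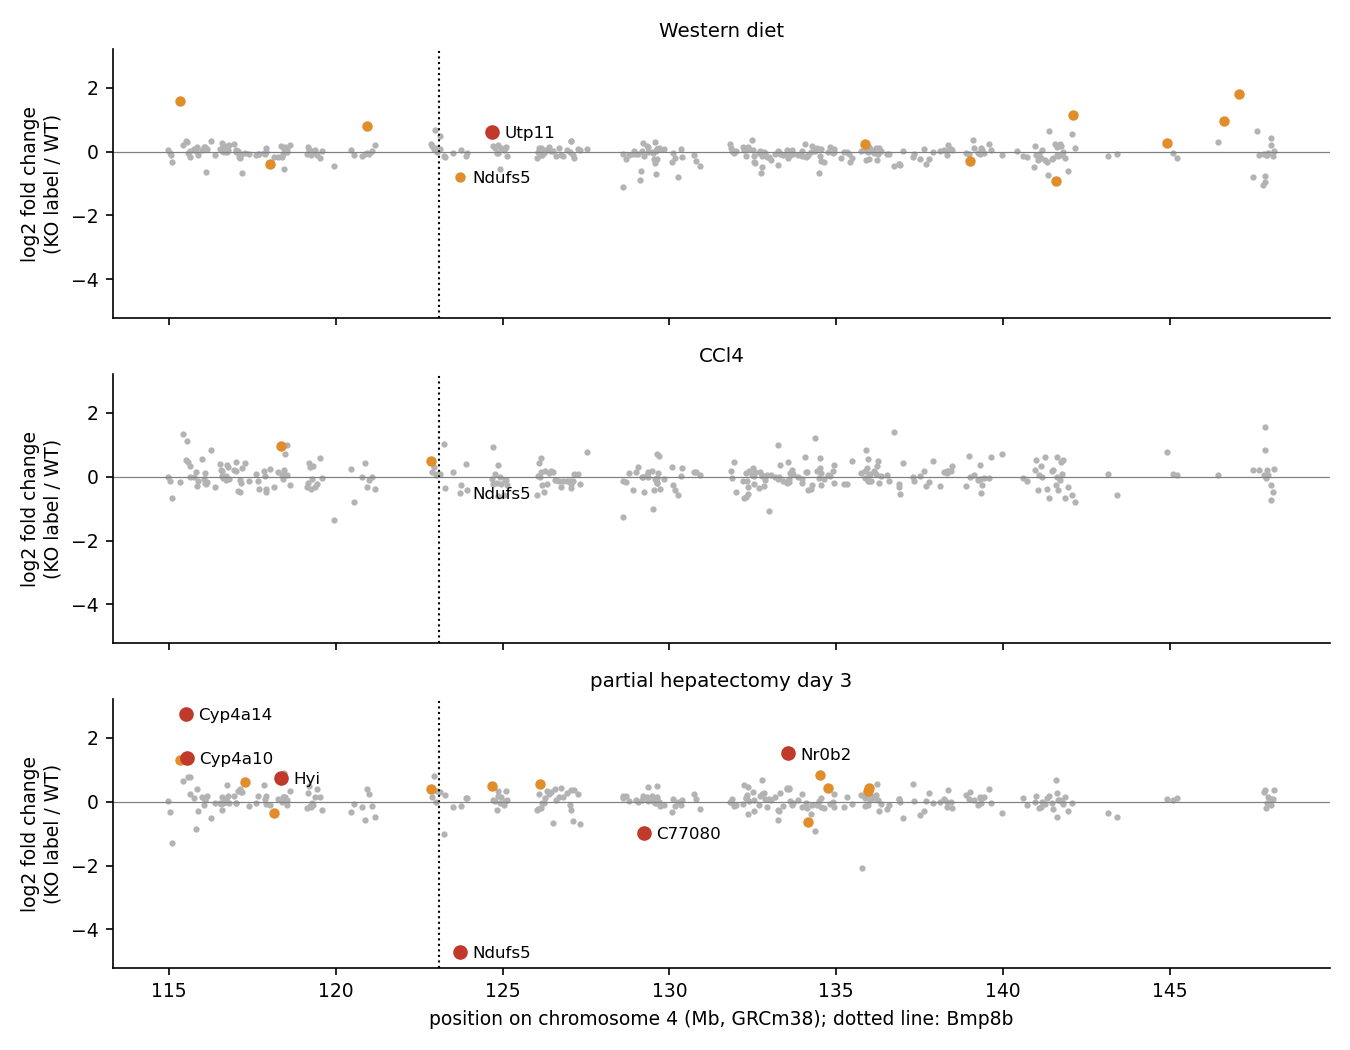
Log2 fold change of labelled knockout over wild-type livers for genes around Bmp8b on chromosome 4, by position in Mb (GRCm38), in the 3 experiments. Red points are called genes, orange points have an unadjusted p under 0.01 and grey points are other tested genes. After hepatectomy Ndufs5 was at -4.69 and C77080 at -0.97.

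The wild-type responses to the 3 challenges were compared with each other. In genes tested in both, 689 rose with both Western diet and CCl4 against 236 if the lists were independent, and 476 fell with both against 192. For CCl4 and hepatectomy, the genes that rose with both were 4.50 times as many as the 112 of independent lists, and 379 fell with both against 74.9. For Western diet and hepatectomy, 544 rose with both against 180 and 365 fell with both against 156. Of 10706 genes tested in all 3 experiments, 340 rose in all 3 against 18.5 if independent, and 211 fell in all 3 against 14.6. The experiments share no libraries. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.616 for Western diet and CCl4, 0.551 for Western diet and hepatectomy and 0.698 for CCl4 and hepatectomy (Spearman's rho 0.492, 0.374 and 0.512).

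The difference between labelled knockout and wild-type livers was tested between challenges in a joint edgeR fit of 12646 genes. No gene differed between Western diet and CCl4, with 1076 genes at an unadjusted p under 0.05 and 19 called by DESeq2. Between Western diet and hepatectomy 2 genes differed, Ndufs5 and Spred1, an inhibitor of growth factor signalling. Between CCl4 and hepatectomy 5 differed, the same 2 genes and Odc1, Ppp4c and Polr1c, all 3 chosen after their values were seen. Odc1, the first enzyme of polyamine synthesis, differed by -1.16 on the log2 scale (edgeR adjusted p = 0.00494), with an effect of -0.81 after CCl4 and 0.34 after hepatectomy. In the fit of the CCl4 and surgery libraries alone, 2 genes differed.

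Across genes, the difference between labelled knockout and wild-type livers correlated negatively with the wild-type response to the same challenge. Both comparisons share the challenged wild-type libraries, which gives a negative correlation with no knockout effect. Only on Western diet was the correlation more negative than simulated, but the covariance was more negative than simulated in each experiment. On Western diet the correlation was -0.641, against -0.512 in simulated groups with no knockout effect. The covariance was -0.105 against a simulated -0.0234. With the challenged wild-type livers split so that no library served both comparisons, the mean correlation was -0.44 and ranged from -0.655 to 0.105 over 70 splits. After CCl4 the unsplit correlation was -0.583 against a simulated -0.587, and -0.17 when split (-0.362 to 0.029 over 6 splits), and the covariance was -0.254 against -0.109. After hepatectomy the unsplit correlation was -0.276 against a simulated -0.473, and -0.096 when split (-0.159 to -0.004 over 20 splits), and the covariance was -0.0682 against -0.0393. On Western diet the livers labelled knockout included liver 1, which lay among the low-fat livers on the first principal component. Wild-type livers 32 and 36 lay between the low-fat livers and the other wild-type livers there. An effect of the label thus cannot be told apart from uneven variation of livers between the groups.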

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

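The tests of explanations in this part were chosen after the results were seen, except the counts of other splits for the hepatectomy comparisons.

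Bmp8b was not lower in the livers labelled knockout, which held 187 counts of it in 17 libraries. Swapped labels of single libraries are argued against by BC002163: on Western diet it separated the labels, and in the other experiments 0 of the 10 libraries labelled knockout were at or below the highest of the 20 wild-type libraries. An exchange of the labels as a whole, in all 3 experiments with their controls, would leave this separation and stays open. Reads from the paralog Bmp8a are argued against, with 1 count of it in the libraries labelled knockout. A transcript left by the targeted allele stays open and cannot be told apart from expression of the intact gene, because gene totals do not place the 187 counts on exons.

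In the livers labelled knockout, BC002163 was higher in all 3 experiments, and called genes lay near Bmp8b on Western diet and after hepatectomy. Their levels (labelled knockout against wild type, CPM ± SD) repeated in part. C77080 was at 91.3 ± 25.3 against 100.5 ± 18.8 on Western diet and 43.5 ± 24.4 against 60.0 ± 14.4 after CCl4. Utp11 was at 24.1 ± 2.27 against 17.1 ± 3.55 after hepatectomy but 17.6 ± 2.79 against 18.5 ± 1.51 after CCl4. Hyi was at 50.3 ± 13.6 against 25.9 ± 12.6 after CCl4. Cyp4a14 and Cyp4a10 overlapped between the labels on Western diet and after CCl4. A candidate explanation is sequence from another strain that came with the targeted allele, and it stays open: the enrichment within 10 Mb after hepatectomy (Fisher's exact p = 7.16e-06) restates the pattern, 0 of 197 genes there were called by edgeR after CCl4 (2 of 197 at an unadjusted p under 0.01, against 160 of 11466 elsewhere), and gene totals hold no sequence variant. BC002163 is 99.4% identical to Ndufs5 over 319 bases with 2 mismatches, and reads of Ndufs5 may be counted at the pseudogene. The sum of both genes differed by 0.12 on the log2 scale on Western diet (95% interval -0.14 to 0.38), while BC002163 held 47.9% of the sum in livers labelled knockout and 2.4% in wild-type livers. Its share was 50.9% against 1.8% after CCl4 and 98.2% against 8.5% after hepatectomy. The sum differed by 0.50 after CCl4 (-0.04 to 1.04, exact permutation p = 0.0714) and by 0.77 after hepatectomy (0.14 to 1.41, exact permutation p = 0.0476, edgeR adjusted p = 0.446), so moved reads may not explain all of the gain there.

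CCl4 livers 34 (wild type) and 35 (labelled knockout) stood apart from the other CCl4 livers, and their shifts correlated at 0.756 across 11663 genes. Over the mitosis genes their mean log2 differences from olive oil were 0.70 and 1.84, and over the neutrophil markers 4.87 and 3.80. The neutrophil markers did not set the pair fully apart. CCl4 wild-type liver 4, which has index D503, was at 3.17 and olive oil liver 26 at 1.80. The remaining CCl4 livers were between -0.41 and 1.31. A difference between index batches stays open: both have index D505 and 7 of the 8 other CCl4 livers have D503, which no olive oil liver has, and their correlation of at most 0.061 with the shift between olive oil livers of D505 and D504 leaves D503 untested except through the single liver 22, which has D504 and was at 4.70 over the mitosis genes, just under the 4.71 to 6.75 of the D503 livers. Exchange with an olive oil liver is argued against, since the mean log2 difference of their drug-metabolizing genes from olive oil was -3.20 in liver 34 and -2.155 in liver 35, with olive oil livers between -0.12 and 0.26. Their total counts, 3699391 and 4346514, lay inside the range of the others, and no biological explanation was tested.

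Of 100 splits of the libraries drawn per comparison, with the real one included, 1 gave as many called genes for Western diet in wild-type livers (4869, highest other 3776), 1 for CCl4 (2331, highest other 197) and 1 for hepatectomy (1915, highest other 29). No other split drawn reached these counts, which argues against chance for them. The 3776 came from a split that put 7 of the 9 low-fat livers in a group and so nearly repeats the real one. For labelled knockout against wild type, 1 split gave as many after hepatectomy (17, highest other 12) and 2 on Western diet (2, highest other 865). These counts were rare among the splits drawn, which argues against chance without excluding it. After CCl4 6 splits gave as many (1, highest other 1858), so chance is not excluded for that count. The 865 and 1858 are far above the real counts of 2 and 1 and point to a structure of the samples: the first set livers labelled knockout 1, 2, 15 and 33 and wild-type livers 5, 32 and 36 apart, and the second left livers 34 and 35 with 4 and 22. Among the 16 hepatectomy splits that part all 5 mouse numbers the real one gave 1915 genes and the others at most 1.

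Of 210 groups of values of named genes, 17 held a library farther from the others than Dixon's 95% critical value allows. Normal and independent values would give about 1 in 20, or 10.5. CPM values need not be normal and genes share libraries, so that rate is only a rough guide. Each value is given with the nearest other library of its group in brackets, in CPM. On low-fat diet, Trem2 was at 1.72 in liver 21 (0.937) and Timp1 at 0.520 in liver 18 (0.094). On Western diet, wild-type liver 5 had Pparg at 40.2 (31.8) and Bmper at 4.89 (2.34), and wild-type liver 32 had Hsd3b5 at 16.4 (2.83). After CCl4, Ugt1a1 was at 81.5 in wild-type liver 4 (53.4) and Bmper at 164.9 in wild-type liver 34 (21.5). At day 0, Mki67 was at 6.03 in liver 15 (1.57), Ccna2 at 4.26 in liver 14 (1.96) and Elovl3 at 744.8 in liver 12 (419.7). At day 3, Lpl was at 192.6 in wild-type liver 12 (100.1), Id2 at 123.7 (77.1) and Id3 at 61.1 (26.1) in wild-type liver 13, and wild-type liver 14 had Glul at 710.5 (501.4), BC002163 at 1.43 (0.387) and Ces1e lowest at 46.8 (61.5). Among the day 3 livers labelled knockout, Id2 was lowest at 82.6 in liver 17 (134.3).

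The effect of the knockout label differed between challenges for 5 genes in the joint edgeR fit. For Ndufs5 the difference was 4.05 on the log2 scale between Western diet and hepatectomy and 4.34 between CCl4 and hepatectomy, for Spred1 -1.20 and -1.43. For Ppp4c it was -0.89, for Odc1 -1.16 and for Polr1c -1.23, each between CCl4 and hepatectomy. The challenges are also different tables, and the hepatectomy table was counted on another annotation. The diet libraries were deeper, at 8963187 counts or more against 6914274 or fewer in the other experiments. The labels give an age of 9 weeks with 32 weeks of diet for the diet mice and 16 weeks for the others. For these genes challenge cannot be told apart from annotation, nor, against Western diet, from depth and age. For Ndufs5, the share of reads counted at BC002163 may also differ between the tables.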

How the results depend on the processing

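The fits within single i5 indexes, those without livers 34 and 35, the edgeR test of Bmp8b with no filter, the unadjusted p under 0.01 and the single libraries left out for genes near Bmp8b, the count of called genes that turned direction and the fatty acid list without its members near Bmp8b were chosen after the data were seen. No called list and none of the 96 called named genes turned its direction in any alternative, while 4 lists with a fry adjusted p over 0.99 did with an estimated correlation, and the cause of the changes below was not tested unless stated. With a fold threshold of 1.5, which asks for larger changes, 990 genes were called for Western diet, 652 for CCl4 and 434 for hepatectomy in wild-type livers, and 1 on Western diet and 2 after hepatectomy for the knockout label. Within D502 1401 genes were called for Western diet and 1 for the knockout label, and within D501, with fewer wild-type libraries, 3645 and 2. For the knockout label, 1 of the calls within each index was among the 2 called with all libraries. For CCl4, 3599 were called with the index as a covariate, a fit that rests on livers 22, 34 and 35, and 4240 within D505, whose lone wild-type CCl4 liver is 34, assumed to vary like the other groups, so neither count checks the index alone. Of the 2331 genes, 82 of 2197 turned direction within D505, 7 with the covariate and 1 each with limma voom, without liver 34 and without 34 and 35, and of the 4869 on Western diet 1 within D501 and 3 within D502, none of them called there. For the knockout label after CCl4, 2 were called by limma voom, 21 by DESeq2, 2 without livers 34 and 35, 0 by edgeR within D503 (734 at an unadjusted p under 0.05), and 1 to 2 with each library left out, 2 without labelled knockout liver 35. After hepatectomy, 182 were called with no filter, 59 by DESeq2 and 3 to 40 with each library left out: 5, 28, 8, 3 and 10 without wild-type livers 12, 13, 14, 15 and 16, and 40, 9, 5 and 3 without labelled knockout livers 17, 18, 19 and 20.

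With the mouse number as a block, hepatectomy in wild-type livers called 1710 genes, 1573 of them among the 1915, and 12 lists against 14. By camera with an estimated correlation, 0 lists passed for Western diet, 7 for CCl4 and 4 for hepatectomy in wild-type livers, and 0 for the knockout label after hepatectomy. By camera with a preset correlation of 0.01, 18, 16 and 17 lists passed for the knockout label on Western diet, after CCl4 and after hepatectomy. With each library left out, 1 to 2 lists passed for the knockout label after CCl4 (2 without wild-type liver 4) and 0 to 3 after hepatectomy (0 without wild-type liver 12 or 13 or labelled knockout liver 19 or 20). The Bmp8b difference at day 3 against day 0 was 1.56 by edgeR with no filter and 0.85 to 1.20 with each library left out, with an exact permutation p of 0.0556 in 6 of these. For the knockout label at day 3 it was 1.28 by edgeR and 0.82 to 1.195 with each library left out, with an exact permutation p of 0.0571 to 0.0893 in 8. DESeq2 called 19, 11 and 39 genes whose knockout effect differed between Western diet and CCl4, Western diet and hepatectomy, and CCl4 and hepatectomy, and the fit of the CCl4 and surgery libraries alone called 2 for the last pair. Among genes changed at least 2-fold, shared rises and falls were 6.75 and 9.91 times those of independent lists for Western diet and CCl4, 8.81 and 25.4 for Western diet and hepatectomy, and 9.75 and 10.3 for CCl4 and hepatectomy. Near Bmp8b on Western diet, Fisher's exact p for called genes was 0.0133 within 5 Mb, 0.0589 within 20 Mb and 0.00077 to 0.032 with each library left out. With genes at an unadjusted p under 0.01 it was 0.0098 within 5 Mb, 0.0511 within 10 Mb and 0.00131 within 20 Mb. After hepatectomy it was 4.71e-05 to 0.0115 with each library left out.

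Of 107 named genes and comparisons, 96 were called. With the fold threshold 25 of these were lost, with robust dispersion 6, with limma voom 3, with 2 groups in the fit 2 of 91 and with DESeq2 1 of 92. With size factors, no filter, a filter of 1 CPM and the block, 0 were lost, and 14 were lost with at least 1 library left out. Depth limits low levels: a count of 0 allows 0.821 CPM in olive oil liver 24. In simulated libraries a 1.5-fold change was recovered in 3.0% of genes for CCl4, 35.8% for hepatectomy and 59.7% for Western diet, and depth, group size and spread all differ between these.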

Other observations

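The readings in this part were chosen after the results were seen. Over the interferon-stimulated genes, the mean log2 differences of single CCl4 livers from olive oil were 0.83, 0.70, 0.35 and 0.70 in wild-type livers 4, 34, 5 and 7, and -0.12, 0.53, -0.03, -0.21, -0.59 and 0.03 in livers labelled knockout 2, 35, 8, 22, 9 and 12, with olive oil livers between -0.23 and 0.18. Over the acute phase genes, livers 34 and 35 were at 2.62 and 3.21, CCl4 wild-type liver 4 at 2.55 and olive oil liver 26 at 2.08. Over the cholesterol biosynthesis genes, livers 34 and 35 were at -2.35 and -1.53 and the other CCl4 livers between -0.23 and 0.57.

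Of the fatty acid oxidation genes measured after hepatectomy, Cyp4a10 and Cyp4a14 lie within 10 Mb of Bmp8b. Without these 2, the 17 others had a fry adjusted p of 0.0325, higher in livers labelled knockout, and adjusted p = 0.141 with an estimated correlation. With all members, fry lost the call in 4 of the 9 fits that left out 1 library.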
